A study of Cyrtotrachelus buqueti with 32 samples.

How the data were processed

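Single-cell RNA sequencing had been carried out on dissociated gut tissue of the bamboo weevil Cyrtotrachelus buqueti. Per the labels, 4 pooled suspensions were made, each from 8 individuals: larval anterior midgut, larval posterior midgut, larval hindgut and adult hindgut. The 32 labelled samples are repeat sequencing runs of these suspensions (10, 9, 7 and 6 runs), so each group is 1 library and no group has a biological replicate. Libraries were made with the 10x Genomics Chromium 3' V3 kit and sequenced on a NovaSeq instrument, per the labels. The deposited matrices hold raw UMI counts per gene and barcode, with the runs of each suspension merged. Cell Ranger 6.1.1 and Seurat are named per the submitters' processing notes, without their roles. The genome build and annotation are not given in the sources used here. All other deposited tables (unit other) held gene identifiers or barcodes. No column of values was left without a sample or group, so 0 were set aside.

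The features were 12569 gene identifiers, each repeated in place of a name. The files do not pair these identifiers with gene names, and no reference was used. The 39 gene lists and cell type marker lists written before the data were examined matched 0 members, so no list result and no cell type name is given, and clusters are numbered. The rule for named genes, also fixed before the data were examined, therefore took at most 2 identifiers higher and 2 lower per comparison. These were the genes with at least 50 CPM in the higher library and the largest bound nearest to 0 of the 95% interval of the log2 ratio. Leading identifiers of a cluster were ranked by fold over all other cells, with a pseudocount of 0.1 per 10000, among genes with a UMI in at least 25% of its cells.

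Barcodes with under 200 genes or under 500 UMIs were left out. This removed 19 barcodes, all from the larval anterior midgut, and every barcode held at least 500 UMIs. A mitochondrial filter could not be applied without gene names. Scrublet, run per library through scanpy 1.11.5, called 3 cells, or 0.0138% of the barcodes that passed, and these were removed. With such a low share the caller may not have worked, so the kept cells may still hold doublets. The labels do not say whether any were removed before deposit. An alternative chosen after seeing the data removed the cells with the highest doublet scores at 0.8% of cells per 1000 cells of a library.

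UMI counts of the kept cells were summed per library and scaled to a library total of 1000000, the CPM used throughout. Each ratio of 2 libraries was given an exact conditional interval at the 95% level, a Clopper-Pearson interval on the split of counts offset by the library totals. A gene was counted as at least 4-fold apart where the CPM ratio was at least 4, the interval bound nearest to 1 was at least 2, the higher library had at least 50 CPM and the summed count was at least 10 UMIs. This is a rule of size and not a test. A gene at 0 in 1 library was given a bound against 3 counts, per library or, within a cluster, over the cluster. All intervals and floors cover counting error only. No p-value, standard error or test is given, since cells and sequencing runs are not replicates.

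Cells of all libraries were clustered jointly without batch correction, since library and group are the same thing here. Counts were scaled to 10000 per cell and log-transformed, 2000 variable genes were chosen with the library as batch key, and 30 principal components, 15 neighbours and Leiden resolution 1 were used. Within a cluster, 2 libraries were compared by the same size rule where each had at least 50 cells. Cluster profiles were also matched between libraries by Pearson's r across 4212 genes of log2 levels with a pseudocount of 10 CPM. These correlations are across genes, which are not independent replicates. Shares of cells carry exact Clopper-Pearson 95% intervals.

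The size rule was tested on simulated counts with counting error only, drawn from the mean gene levels of each pair and the real library totals. Variation between cells was not simulated, and changed genes were taken from genes above a minimum level. In each of the 4 comparisons, run on 12569 genes with 200 changed, 0 unchanged genes were called. All 50 of 50 genes were called at each of 6-fold, 8-fold and 16-fold, and 0 of 50 at 2-fold. At these depths such calls were close to fixed in advance. They check the arithmetic of the rule and not its error rate in real cells. Interval coverage was 96.1% for posterior against anterior midgut, 95.9% for hindgut against posterior midgut, 96.2% for hindgut against anterior midgut and 95.7% for adult against larval hindgut. The ranking of leading genes placed 20 of 20 raised genes in its top 20 in simulated cells of the larval hindgut profile, also over 12569 genes.

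Alternatives fixed in advance were edgeR 4.0.16 TMM factors, DESeq2 1.42.0 median-of-ratios size factors, no CPM minimum, a 200 CPM minimum, all deposited barcodes, the mean over cells of each cell's UMI share, and totals without the 50 most abundant genes of each library. For shares of cells they were resolutions of 0.5 and 2, separate clustering of each library, all barcodes with at least 200 genes, and thinning to 1000 UMIs. Both R packages were used for scaling factors only. Alternatives chosen after seeing the data were cells with at least 1000 UMIs, removal of the highest doublet scores, and removal of clusters 5, 20 and 24. Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and R 4.3.3 were used.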

Results

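The intestine of Cyrtotrachelus buqueti, a weevil whose larvae and adults feed on bamboo shoots, was profiled by single-cell RNA sequencing in 3 larval regions and 1 adult region. The larval anterior midgut library held 1784 kept cells and 12592060 UMIs, the larval posterior midgut library 10568 cells and 32212532 UMIs, the larval hindgut library 3920 cells and 32255577 UMIs, and the adult hindgut library 5504 cells and 26513076 UMIs. Median UMIs per cell were 2147, 1562, 1819 and 1832 in the same order, and median genes per cell were 785.5, 851, 893.5 and 840.0. Each library is 1 pool of 8 individuals, so no difference below has a replicate check, and every interval covers counting error only. A count of 3 UMIs, the floor used for genes at 0, corresponds to 0.238 CPM (UMIs scaled to a library total of 1000000) in the anterior midgut and 0.0931 CPM in the posterior midgut.

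Pearson's r of log2 CPM across genes was highest for the 2 hindgut libraries, at 0.694 over 3557 genes, and lowest for posterior midgut with adult hindgut, at 0.382 over 3727 genes. The 2 larval midgut libraries gave only 0.428 over 3709 genes, below the 0.671 of posterior midgut with larval hindgut and the 0.587 of anterior midgut with larval hindgut. Other measures order the pairs differently. The share of genes at least 4-fold apart was 7.16% for posterior midgut with larval hindgut and 8.74% for the hindgut pair, and the median r of matched clusters was 0.761 and 0.564. Genes are not independent replicates, so these coefficients describe the libraries and were not tested.

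The first comparison asked how the 2 regions of the larval midgut differ. EVM0007892 and EVM0005453 were abundant in the posterior midgut and almost missing from the anterior midgut. EVM0007892 stood at 14681 CPM against 2.54 CPM, a ratio of 5777 (95% interval 4092 to 8446), and EVM0005453 at 12838 CPM against 3.81 CPM, a ratio of 3368 (2540 to 4568). In the other direction, EVM0009277 reached 6102 CPM in the anterior midgut from 76833 UMIs and 0.0931 CPM in the posterior midgut from 3 UMIs, a ratio of 65517 (22418 to 317706). EVM0000776 stood at 3609 CPM against 0.373 CPM, a ratio of 9688 (5545 to 18750). The sizes of these ratios depended on the weight given to each cell. With UMI shares averaged over cells, the log2 ratios of EVM0007892 and EVM0005453 were 9.94 and 9.16 against 12.50 and 11.72 in the main setting, and 13.73 and 12.99 with cells of at least 1000 UMIs. Those of EVM0009277 and EVM0000776 were 19.06 and 12.36 with averaged shares, above and below their counting intervals. Only the directions held in every alternative.

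By the size rule, 581 genes were at least 4-fold apart between the midgut regions, 333 higher in the posterior and 248 higher in the anterior midgut. Without the CPM minimum the balance turned, with 708 higher in the posterior and 870 higher in the anterior midgut. The 581 genes were 15.7% of the 3709 genes with at least 50 CPM in either library, and 58.7% of the 3709 were within 2-fold. The genes higher in the anterior midgut came mostly from 1 cluster each: 220 of the 248 drew over 50% of their anterior midgut UMIs from a single cluster, and for 163 the largest contributor was cluster 6. Cluster 6 held 534 of the 1784 anterior midgut cells and none of the 10568 posterior midgut cells. EVM0009277 and EVM0000776 lead this cluster and drew 99.1% and 99.2% of their anterior midgut UMIs from it. Of the genes higher in the posterior midgut, 33 of 333 drew over 50% from 1 cluster. The counts of 220 and 33 depend on how finely each library was split, so they do not compare breadth of expression. Cluster 6 alone held 37.6% of the anterior midgut UMIs. Several posterior midgut clusters had similar profiles, such as 15 and 16 (r = 0.924) and 22 and 24 (r = 0.947). EVM0007892 drew 54.9% of its UMIs from cluster 18, where it was at 82860 CPM against 7329 CPM in the other posterior midgut cells, and free RNA was not separated from expression in the latter. Within the 3 clusters with at least 50 cells of both regions, 218 of the 581 genes were also at least 4-fold apart in the same direction in 1 or more clusters, 169 higher and 49 lower in the posterior midgut. Only 39 of the 169 and 28 of the 49 were also at or above their whole-library level there. At lower levels free RNA was not separated from expression. For cluster 1, which is among the 3, the anterior midgut profile matched posterior midgut clusters 1 and 19 equally well, with r = 0.610 for each. Whether like cells were compared in cluster 1 is therefore not known. The anterior midgut library had fewer UMIs than the posterior midgut library (12592060 against 32212532), which widens the intervals of genes near its floor.

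**Figure D1:**
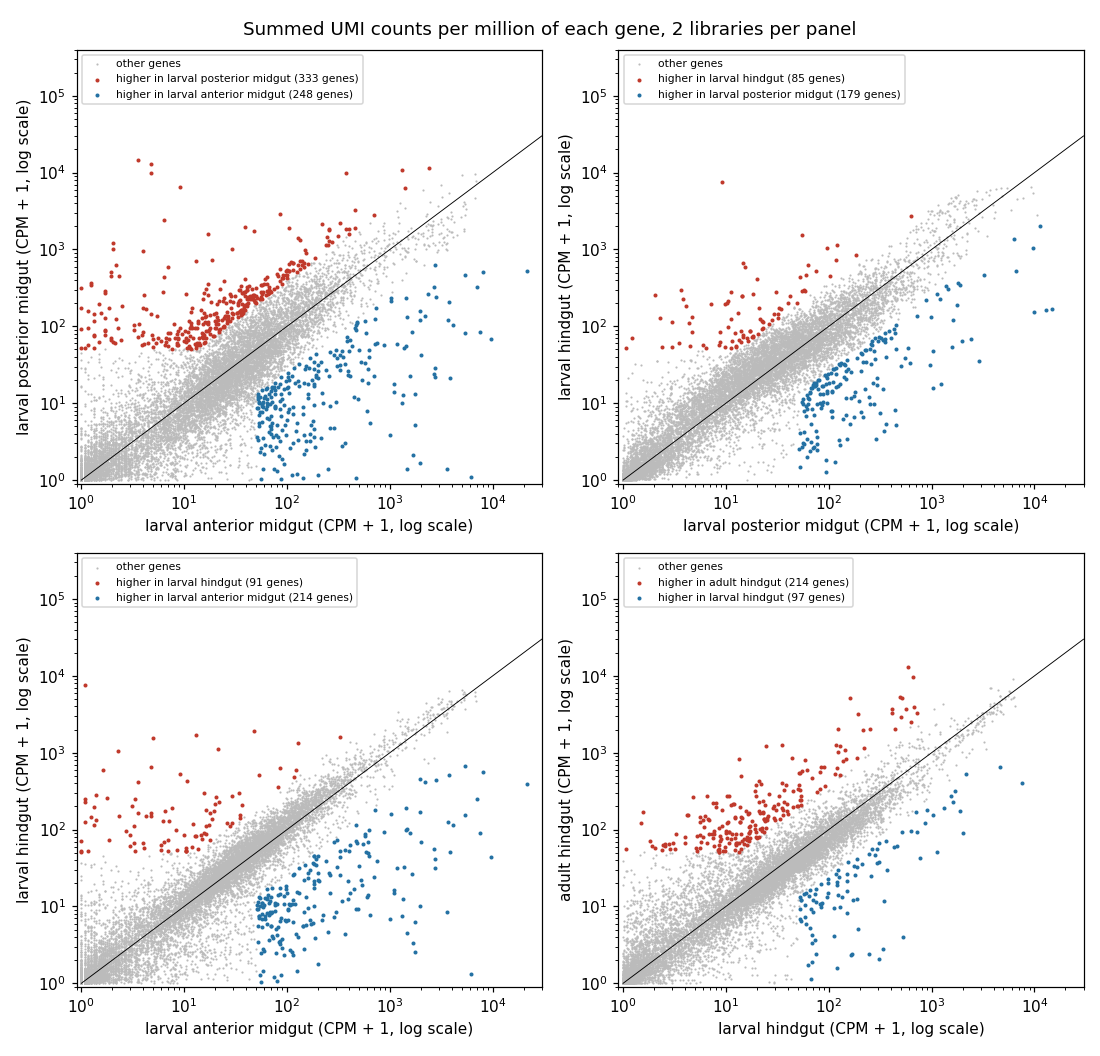
Each point is 1 gene, plotted by its CPM plus 1 in 2 libraries on log axes, for the 4 comparisons; red and blue points meet the size rule in either direction and the line marks equal levels. The midgut pair has 333 and 248 such genes and scatters most among these 4 pairs (r = 0.428), and the hindgut pair has 214 and 97 (r = 0.694).

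The next comparison set the larval hindgut against the posterior midgut. EVM0002646 was the gene that set the larval hindgut apart most, at 7629 CPM against 8.07 CPM, a ratio of 945 (837 to 1072). EVM0009814 was scarcer, at 51.8 CPM against 0.0621 CPM, a ratio of 834 (230 to 6891) that rests on 2 posterior midgut UMIs. EVM0001650 and EVM0004358 were higher in the posterior midgut, at 92.5 CPM against 0.279 CPM (ratio 332, 174 to 726) and at 115 CPM against 0.713 CPM (ratio 161, 107 to 255). With averaged UMI shares the log2 ratios of EVM0002646, EVM0001650 and EVM0004358 fell to 8.79, 7.10 and 6.65 from 9.88, 8.37 and 7.34, the last 2 toward the posterior midgut.

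In all, 264 genes were at least 4-fold apart in this pair, 85 higher and 179 lower in the larval hindgut. The split was 63 and 215 with median-of-ratios factors, 109 and 155 with UMI shares averaged over cells, and 422 and 418 without the CPM minimum. In the main setting, 69.3% of 3685 genes were within 2-fold. Of the 85 genes higher in the larval hindgut, 76 drew over 50% of their UMIs from 1 cluster, with cluster 12 the largest contributor to 21 and cluster 7 to 19. Cluster 12 held 17.2% of all larval hindgut UMIs and cluster 7 held 46.5%. Cluster 7 was thus the largest contributor to a smaller share of these genes (22.4%) than its share of UMIs. EVM0002646 leads cluster 12 and drew 98.4% of its hindgut UMIs from it. It had a UMI in 80.2% of the hindgut cells of that cluster and in 45.8% of the other hindgut cells, whose median depths were 9615 and 1552 UMIs. EVM0009814 drew 97.9% of its UMIs from cluster 29 and had a UMI in 43.1% of its cells against 0.724% of the others, at median depths of 1783 and 1819. Among the 179 genes higher in the posterior midgut, 17 drew over 50% from 1 cluster, and cluster 18 was the largest contributor to 72. The count of 17 also depends on the split of the posterior midgut into clusters with similar profiles. In the 2 clusters that could be compared within, 76 of the 264 genes were again at least 4-fold apart, 13 higher and 63 lower in the hindgut. Of these, 3 of the 13 and 0 of the 63 were at or above their whole-library level, so the 63 are not separated from free posterior midgut RNA.

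Against the anterior midgut, the larval hindgut was again set apart by EVM0002646, with 246077 UMIs against 1, a ratio of 96065 (17242 to 3794360). EVM0004839 stood at 248 CPM in the hindgut and had 1 UMI in the anterior midgut, a ratio of 3119 (560 to 123200). EVM0009277 and EVM0009293 were higher in the anterior midgut, at ratios of 19681 (10701 to 41044) and 1112 (845 to 1493). Levels of EVM0009293 were 1758 CPM in the anterior midgut and 1.58 CPM in the larval hindgut. Averaged UMI shares lowered the log2 ratios of EVM0009277 and EVM0009293 to 12.82 and 8.56 from 14.26 and 10.12.

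By the size rule 305 genes were apart in this pair, 91 higher and 214 lower in the larval hindgut (411 and 696 without the CPM minimum), while 80.3% of 3547 genes were within 2-fold. The median log2 ratio over those 3547 genes was 0.26, a shift toward the hindgut that the size rule does not remove. When each cell's UMI share was averaged instead of summing UMIs, 160 genes were higher and 219 lower, so the higher share went from 29.8% to 42.2%. Cluster 6 was the largest contributor to 144 of the 214 genes higher in the anterior midgut. Clusters 12 and 17, with 17.2% and 9.16% of the larval hindgut UMIs, were each the largest contributor to 25 of the 91 genes higher in the hindgut. EVM0004839 drew 72.5% of its hindgut UMIs from cluster 17. Within the 6 clusters with enough cells of both libraries, 99 of the 305 genes were also at least 4-fold apart, 42 higher and 57 lower in the hindgut, and 23 of the 42 and 28 of the 57 were at or above their whole-library level.

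**Figure D2:**
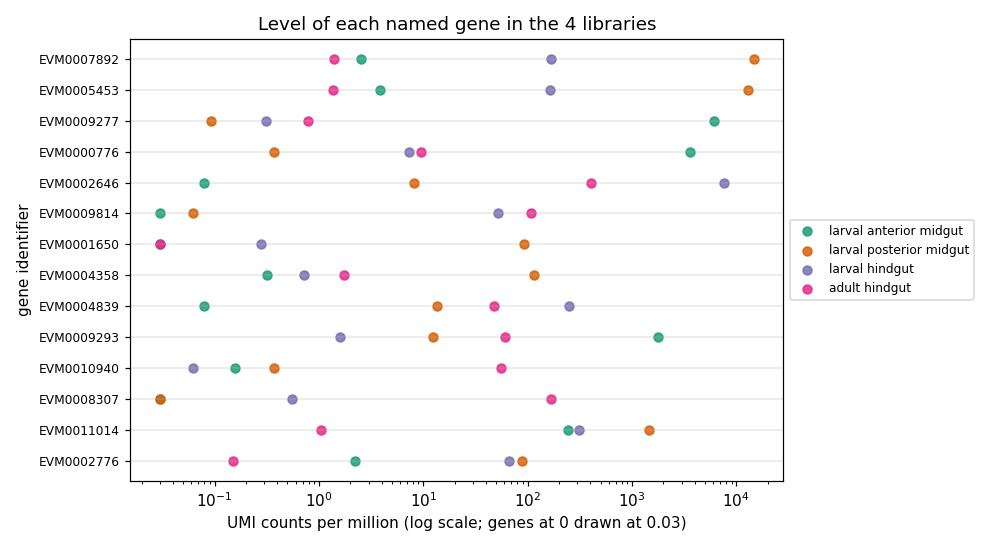
Each point is the level of 1 named gene in 1 library, in CPM on a log axis, with genes at 0 drawn at 0.03. EVM0002646 spans 0.0794 CPM in the anterior midgut to 7629 CPM in the larval hindgut, and EVM0011014 is at 241 CPM or more in the 3 larval libraries and at 1.06 CPM in the adult hindgut.

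Adult and larval hindgut were compared to describe the difference between stages of 1 region. EVM0010940 was higher in the adult, at 55.5 CPM against 0.0620 CPM, a ratio of 895 (247 to 7396) that rests on 2 larval UMIs. EVM0008307 stood at 167 CPM against 0.558 CPM, a ratio of 300.0 (190 to 507), with 0 UMIs in both midgut libraries. EVM0011014 and EVM0002776 were higher in the larva, at 309 CPM against 1.06 CPM (ratio 293, 203 to 441) and 65.6 CPM against 0.151 CPM (ratio 435, 170 to 1598). Averaged UMI shares lowered the log2 ratios of EVM0008307 and EVM0011014 to 6.58 and 7.63 from 8.23 and 8.19, the latter toward the larva.

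The stages were at least 4-fold apart in 311 genes, 214 higher and 97 lower in the adult (821 and 377 without the CPM minimum), and 78.6% of 3557 genes were within 2-fold. The median log2 ratio of the 3557 genes was -0.25. Cluster 28 was the largest contributor to 58 of the 214 genes higher in the adult and cluster 27 to 48, with 17.3% and 7.31% of the adult UMIs. EVM0010940 drew 64.4% of its adult UMIs from cluster 27, and EVM0008307 drew 94.6% from cluster 32. Of the 97 genes higher in the larva, 34 had cluster 17 as their largest contributor, 25 cluster 12 and 19 cluster 7. These clusters held 9.16%, 17.2% and 46.5% of the larval hindgut UMIs, so cluster 7 contributed less often (19.6%) than its share of UMIs. EVM0002776 drew 98.7% of its larval hindgut UMIs from cluster 11, where it reached 3926 CPM, against at most 4.71 CPM in any adult cluster. It had a UMI in 24.7% of the larval hindgut cells of cluster 11. The adult value rests on 1 UMI in cluster 11, whose 43 adult cells were too few for a comparison within the cluster. Whether the adult library held like cells is not known. The levels of EVM0011014 ranged from 10.5 to 1055 CPM over 19 larval hindgut clusters and from 0 to 4.85 CPM over 17 adult clusters, each of at least 10 cells. The larval median over clusters was 127 CPM, and free RNA was not separated from expression in clusters with low levels. The highest larval value rests on 17 UMIs in cluster 20, 99.1% of whose cells were posterior midgut, and the lowest on 1 UMI in cluster 33. Within the 8 clusters with enough cells of both stages, 145 of the 311 genes were also at least 4-fold apart, 95 higher and 50 lower in the adult, and 56 of the 95 and 35 of the 50 were at or above their whole-library level. In clusters 8 and 30, which are among the 8, adult and larval profiles were not each other's best match. Whether like cells were compared in those clusters is not known.

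Joint clustering gave 34 clusters, of which 20 drew at least 90% of their cells from 1 library and held 62.7% of all cells. With 1 library per group, such a cluster may be that library and not a cell type. Clusters 2, 3, 11 and 12 had at least 10 cells of every library. They held 28.2% (26.1 to 30.3) of the anterior midgut cells, 4.11% (3.74 to 4.50) of the posterior midgut, 22.1% (20.9 to 23.5) of the larval hindgut and 7.59% (6.91 to 8.33) of the adult hindgut. The posterior midgut share was 8.76% at resolution 0.5, 9.05% with each library clustered on its own and 8.08% with cells thinned to 1000 UMIs, so its size depended on how the cells were grouped. On its own, the larval hindgut gave 13.6%. Cluster 2 was led by EVM0011791, which was at 90175 CPM in its anterior midgut cells and at 54038 CPM in its larval hindgut cells, against 84.7 and 10.2 CPM in the other cells of those libraries. In cluster 3 the leading gene EVM0005009 was at 6852, 2329, 5190 and 4213 CPM in the anterior midgut, posterior midgut, larval hindgut and adult hindgut. Clusters 11 and 12 did not keep their first gene in every library. In the same order, EVM0001473 of cluster 11 was at 33950, 2772, 1494 and 0 CPM and EVM0002646 of cluster 12 at 0, 245, 43663 and 30045 CPM. Of their 10 leading genes, 8 in adult cells of cluster 11 and 9 in anterior midgut cells of cluster 12 were still at least 4-fold above the rest.

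**Figure D3:**
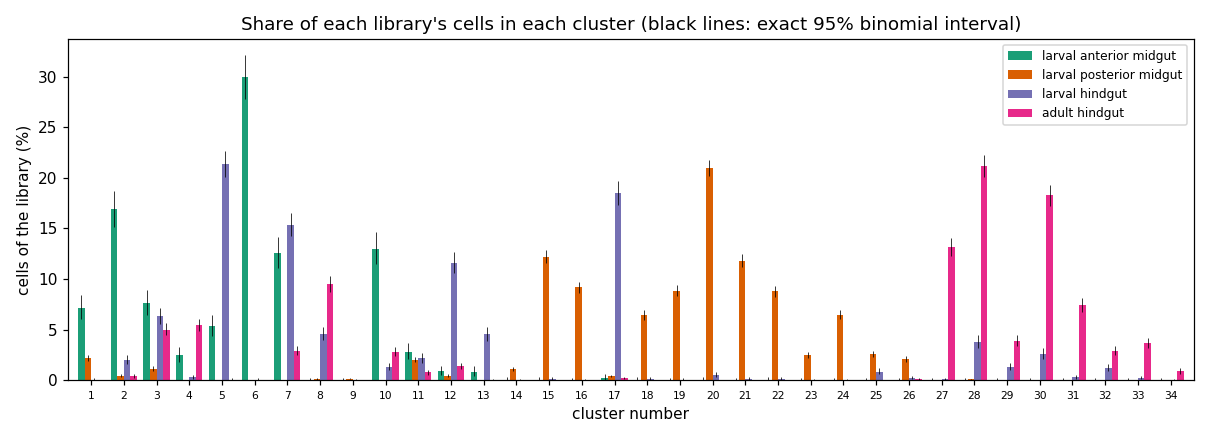
Bars give the percent of each library's cells in each of the 34 numbered clusters, with exact 95% binomial intervals as black lines. Cluster 6 holds 29.9% of the anterior midgut cells and 0% of posterior midgut and adult hindgut cells, and clusters 27 and 28 hold 13.1% and 21.1% of the adult hindgut cells.

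Some clusters without posterior midgut cells had a mutual best match there, and others did not. Cluster 7, with 224 anterior midgut, 601 larval hindgut and 161 adult hindgut cells, had 0 of 10568 posterior midgut cells. The floor of 3 counts corresponds to a share of 0.0284%, and the exact interval reaches 0.0349%. Its larval hindgut profile matched posterior midgut cluster 15 with r = 0.805 across 4212 genes, and each was the other's best match. Cluster 10, led by EVM0001007 and EVM0002385, likewise had 0 posterior midgut cells, and its anterior midgut profile matched posterior midgut cluster 14 with r = 0.576. The larval hindgut profile of cluster 5 matched posterior midgut cluster 20 with r = 0.820, and neither of these 2 clusters had a gene at least 4-fold above the rest of its library. Clusters 6 and 4, also with 0 posterior midgut cells, had no such pair: cluster 6 of the anterior midgut was nearest to posterior midgut cluster 11 with r = 0.506 and cluster 4 of the adult hindgut to cluster 3 with r = 0.197, and in both cases the best match in return was another cluster. A missing library in a joint cluster was therefore not read as a missing kind of cell.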

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

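The tests of matched clusters, of shared barcodes and of genes higher in larval cells were chosen only after the result was seen; the comparison of medians for carried-over adult cells was written beforehand.

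Among the 8 clusters in which adult and larval hindgut cells could be compared, 190 genes were at least 4-fold apart in 2 or more clusters, and 42 of them (22.1%) were higher in the adult in 1 cluster and higher in the larva in another. The 2 directions within 1 contrast drew attention to this result. The difference between clusters was not tested, since each stage is 1 library. In clusters 8 and 30 the adult and larval cells were not each other's best match by profile, so whether like cells were compared there is not known; over the 6 matched clusters the number was 24, and only 7 of these were at or above their library level in both directions, which leaves free RNA open for the rest. EVM0009989, chosen after its values were seen, is 1 of the 7, at 187 CPM in adult and 1943 CPM in larval cells of cluster 3, and at 617 CPM in adult and 140 CPM in larval cells of cluster 12.

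Larval hindgut cells were found in 9 of the 10 clusters that were mostly adult: 570 cells, 14.5% of that library (13.5 to 15.7). Index swapping of adult molecules is argued against by barcodes, since 0.351% of these cells, or 2 cells, had a barcode of the adult list. Carried-over adult cells were first weighed by whether genes lower in larval cells fell further than the leading genes of their cluster, with a smallest difference of 0.625 in median log2 ratio over clusters 8, 28, 29 and 30; that test decides nothing, since its genes were chosen as at least 4-fold lower. A second test, added after its counts were known, took all genes 4-fold higher in larval than adult cells of clusters 28 and 29, which are matched. Of these genes, 38 of 59 in cluster 28 and 41 of 55 in cluster 29 were at or above their larval library level. Adult cells that hold only free larval RNA would not reach that level if free RNA had the composition of the summed library. That composition was not measured, and the genes were picked out by their levels in these same cells, so this test does not decide either. Carried-over adult cells stay open as the source of some or all of the larval cells in the mostly adult clusters. The difference in stage is a possible explanation that was not tested.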

How the results depend on the processing

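The alternatives with cells of at least 1000 UMIs, without the highest doublet scores and without clusters 5, 20 and 24 were chosen after seeing the data. No paired analysis was possible because each group is 1 pooled library and its run numbers are technical. Of 144 alternative values for the gene counts and cell shares, 109 stayed within their bounds and 35 moved. A changed CPM minimum moved every count by admitting or dropping genes. Without a minimum, totals, higher and lower counts were 1578, 708 and 870 for posterior against anterior midgut, 840, 422 and 418 for hindgut against posterior midgut, 1107, 411 and 696 for hindgut against anterior midgut, and 1198, 821 and 377 for adult against larval hindgut. At 200 CPM they were 260, 157 and 103, then 107, 31 and 76, then 120, 31 and 89, then 116, 80 and 36. Averaging UMI shares over cells gave 160 genes higher in hindgut than anterior midgut; the cause was not tested. The share of cells in clusters 2, 3, 11 and 12 moved as follows, and the cause was not tested. Separate clustering gave 20.7% in anterior midgut, 9.05% in posterior midgut and 13.6% in larval hindgut. Thinning to 1000 UMIs gave 26.1%, 8.08%, 18.4% and 8.35% in anterior midgut, posterior midgut, larval hindgut and adult hindgut; it left out 482, 2651, 1368 and 1742 cells, and the unthinned shares of the same cells were 24.7%, 4.53%, 24.5% and 8.88%. Resolution 0.5 gave 8.76% in posterior midgut, resolution 2 gave 17.2% in larval hindgut, and removing the highest doublet scores gave 20.2% there. Median-of-ratios factors shifted all log2 ratios of hindgut against posterior midgut by -0.21 and TMM factors by -0.12; the other comparisons shifted by 0.11, -0.10 and 0.12 with median-of-ratios factors. Of 128 alternative values for the named genes, 114 lay inside the counting interval, 14 outside it and 0 changed direction. Of 70 for sets of genes across libraries, 56 stayed within 1.5 times and 14 moved, 13 of them with another CPM minimum. Removing the highest doublet scores turned 1 gene, EVM0006435, from higher in the anterior midgut to higher in the larval hindgut, as its anterior midgut UMIs went from 7760 to 49. Alternatives for gene lists were not run because the lists matched 0 members. Depth limits the anterior midgut most, where 3 UMIs are 0.238 CPM.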

Other observations

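The tests on shallow cells and on genes at or above their library level were chosen only after the result was seen; the tests of free RNA by median level and by ratio to cluster 11 were written beforehand.

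Several sets of genes separated regions and stages jointly, and their sizes depended on the CPM minimum. The anterior midgut was at least 4-fold above both other larval libraries for 192 genes, the posterior midgut for 149 and the larval hindgut for 50 (549, 268 and 182 without the minimum). Comparisons that share a library are not independent. Independent lists would overlap in 18, 19.9 and 2.45 genes, which is no reference here, since both lists share the higher library. Simulated libraries with no difference gave 0 genes in each set. They held counting error only, so this outcome was fixed in advance and does not bear on the sizes of the sets. Both hindgut libraries were above both midgut libraries for 21 genes (96 without the minimum and 35 with UMI shares averaged over cells), with EVM0012113 at 229 CPM in the larval and 433 CPM in the adult hindgut against 0.0794 and 2.82 CPM in anterior and posterior midgut. In the main setting 3 genes were higher in both midgut libraries than in both hindgut libraries, and 21 without the minimum; EVM0012166 stood at 202 and 295 CPM in the midgut and 20.6 and 10.5 CPM in the hindgut. The adult hindgut was above all 3 larval libraries for 106 genes (316 without the minimum). For 22 genes (87 without the minimum) all 3 larval libraries were above the adult hindgut, among them EVM0011524 at 974, 1367 and 337 CPM in anterior midgut, posterior midgut and larval hindgut and 1.77 CPM in the adult.

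EVM0008496, chosen after its values were seen, had 0 UMIs in the whole anterior midgut library against 44.4 to 1209 CPM over the 20 clusters with at least 10 posterior midgut cells; its highest levels were in clusters 18 and 25, and free RNA was not separated from expression in the others. In 49 genes the anterior midgut had at most 3 UMIs while another library had at least 50 CPM, against 11 such genes for the posterior midgut, 3 for the larval hindgut and 9 for the adult hindgut. The anterior midgut had the fewest UMIs in all; at 1 limit of 0.238 CPM for all 4 libraries the numbers were 49, 18, 4 and 15. EVM0006435, also chosen after its values were seen, had 7760 anterior midgut UMIs, of which 99.4% lay in 1 cell.

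Clusters 5, 20 and 24 had no gene at least 4-fold above the rest of their library, which held for larval hindgut cells of cluster 5 and posterior midgut cells of clusters 20 and 24. For cluster 5, genes leading other clusters were below their level in the rest of the library by a median log2 ratio of -1.42. This argues against droplets that hold only free RNA with the composition of the rest of the library. The composition of free RNA was not measured, so free RNA of another composition stays open. The profile of cluster 5 was nearer to the deeper cluster 7 than to the rest by 0.0411 in r, so shallow cells of cluster 7 are a candidate explanation. For cluster 20 the same values were -0.767 and -0.00548, both between the bounds set for either outcome, so these explanations cannot be told apart there. For cluster 24 the median was -0.0327 and the gain in r was 0.0483 toward cluster 22, so free RNA and shallow cells of cluster 22 both stay open. No biological explanation was tested.

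Within cluster 3, 190 genes were at least 4-fold higher in posterior than anterior midgut cells. Of these, 41 were at or above their level in the whole posterior midgut library; they were picked out by that level, so their number is not a test of free RNA. The other 149 genes had a median level of 0.245 of the library, and the ratio of their cluster 3 to cluster 11 levels was within 2-fold of its median for 89.3% of them. A single shared source would give this, but the share for other genes was not taken and these genes were selected by level, so it does not decide. Free RNA stays open for those 149, and a difference between midgut regions in these cells was not tested for them.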
